A study of Mus musculus with 8 samples.

How the data were processed

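Messenger RNA was measured in 8 libraries of CD4+ T cells from C57BL/6 mice, in 4 groups of 2. Per the labels, naive cells were taken from spleen and lymph nodes, and the other 3 groups were activated through CD3e and CD28 and polarized for 3 days with TGF-beta and IL-6, alone, with the synthetic lipopeptide PAM3CSK4 or with the proteoglycan biglycan. The dose of 2 ug/ml in the series text belongs to PAM3CSK4; whether it also applies to biglycan is not clear from that text. Per the labels, RNA was purified with a Qiagen kit and libraries were made with a stranded mRNA kit from Illumina.

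Reads were aligned and counted with Bowtie2 and HTSeq against mouse build mm9, per the submitters' processing notes. Their versions, the annotation and the strand setting of the counting are not given in the sources used here. The deposited table holds raw counts per gene, whole numbers without normalization, for 23366 gene symbols. Its 5 summary lines, which name no gene, were left out of library sizes and tests. The line for reads without a unique alignment held 73.4 to 77.1% of each library's total in that table, and genes held 11.7 to 13.7%. These are shares of the table's total, which exceeds the number of read pairs, and not shares of reads. In naive replicate 1, for example, 7012244 gene counts were 12.2% of that total, while the library had 24086378 read pairs. The deposited mapping tables give the percent of reads that mapped and the percent assigned to ribosomal and mitochondrial RNA, per the file headers. These were used to describe the libraries only. The deposited normalized counts, RPKM values and coverage per chromosome were not used here.

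Each column was linked to its sample through its name and the library number that the deposited mapping table pairs with it. The biglycan columns carry the numbers 5 and 6 in the count table, while the titles of the same library numbers carry 7 and 8; the numbers of the titles are used here. Nothing in the labels says that the 2 libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical. No replicate pair agreed within sampling noise: the chi-square per degree of freedom between the 2 libraries of a group was 6.15 in naive cells, 4.56 in Th17, 4.54 with PAM3CSK4 and 2.69 with biglycan.

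Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, which left 11629 tested genes, and libraries were scaled with TMM factors. One quasi-likelihood model with a mean per group was fitted to all 8 libraries (glmQLFit, glmQLFTest), so that all groups shared 1 estimate of the spread with 4 residual degrees of freedom. The common biological coefficient of variation was 6.19% and the prior degrees of freedom were 15.9. The comparisons made were these: Th17 with naive cells, PAM3CSK4 with Th17, biglycan with Th17, and PAM3CSK4 with biglycan. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Levels are CPM, counts scaled by TMM-adjusted library size, computed here from the deposited counts. Log2 fold changes are given ± standard error.

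Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Of 35 lists, 32 had at least 5 tested members; the lists of myeloid, gamma-delta T cell and red cell markers did not, and only their member counts are given. Each call was repeated with the correlation estimated per list and with fry, whose directional p asks whether a list's genes move in a common direction on balance without comparing them with other genes. Some estimates lay under the preset although the call ended: -0.0130 for NF-kB targets with PAM3CSK4 against Th17, and -0.0142 for IL-2 and STAT5 targets with biglycan. The larger p of such lists does not come from correlated members, so the 2 versions differ in more than the correlation. The samples of each group, the tests, the gene lists, the rule for named genes and all alternatives but the offsets and the split named below were chosen before the data were examined. The rule allowed, per comparison, up to 10 genes with the largest rise and 10 with the largest fall among called genes with at least 5 CPM in the higher group and libraries that did not overlap; up to 4 members of each list, the 2 that rose and the 2 that fell with the smallest p; 17 genes of interest such as Il17a, Tlr2 and Bgn; and, where fewer than 5 genes passed in a direction, the 5 with the smallest p, as values. Some genes that the rule allows are not reported here.

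A fold against a group with 0 counts is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts a ratio of CPM with its 95% counting interval is given. Such intervals and floors cover counting error only. Library totals ran from 7012244 to 12533045 counts, so that 3 counts in 1 library correspond to 0.239 to 0.428 CPM. The whole procedure was tested on simulated counts with seeded changes. For PAM3CSK4 against Th17 it recovered 34.3% of genes changed 1.25-fold, 82.1% of those changed 1.5-fold and 98.5% of those changed 2-fold, with 11 false calls among 154. For biglycan against Th17 these shares were 32.8, 82.1 and 100%, with 6 false calls among 149. For Th17 against naive they were 20.9, 79.1 and 97.0%, with 9 among 140, and for PAM3CSK4 against biglycan 20.9, 83.6 and 100%, with 16 among 152. Recovery was not measured separately for genes with few counts. The shares therefore do not give the power for genes at a low level, such as Tlr2, Csf2, Il2 and Tbx21. A change in such genes may have been missed more often, also with biglycan.

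Alternatives were RLE size factors, library totals alone, no filter on low counts, only the libraries compared, only the 6 polarized libraries, robust estimation, DESeq2 1.42.0 and leaving out each library in turn. Leaving out a library left its group with 1 library, which was assumed to vary like the others. For Th17 against naive, the only groups that share replicate numbers, a fit with the number as a block was also made. Offsets for GC content and transcript length, chosen after the data were seen, were taken by gene symbol from GENCODE M21 transcripts of GRCm38, a different build from that of the counts, so no coordinates are given. They covered 99.3% of tested genes. For the overlap of the PAM3CSK4 comparisons, a split also chosen after the data were seen set 1 PAM3CSK4 library against Th17 and the other against biglycan, each called in the fit that left out the other library. Genes that overlap or lie antisense to another, such as small nucleolar RNAs inside their host genes, and near-identical copies, such as the histone and Hspa1 genes, are uncertain because the strand setting and the handling of shared reads are not stated.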

Results

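The data are gene counts from 8 libraries: naive CD4+ T cells (replicates 1 and 2), Th17 cultures (1 and 2), Th17 cultures with PAM3CSK4 (3 and 4) and Th17 cultures with biglycan (7 and 8). PAM3CSK4 is a synthetic lipopeptide that activates the receptor pair TLR2 and TLR1, and biglycan is a matrix proteoglycan that can act as an endogenous ligand of TLR2 and TLR4. Gene counts summed to 7012244 and 8029382 in the naive libraries, 11788948 and 10207664 in Th17, 12533045 and 11107155 with PAM3CSK4, and 9361343 and 9360830 with biglycan. Between 12847 and 13774 genes had at least 1 count per library. Mitochondrial RNA took 10.9 ± 1.5% of reads in naive cells (mean ± SD, n = 2 here and for all values below), 15.9 ± 0.215% in Th17, 14.5 ± 0.322% with PAM3CSK4 and 16.01 ± 0.136% with biglycan. Ribosomal RNA took 1.99 ± 0.0998, 2.66 ± 0.129, 2.38 ± 0.924 and 1.66 ± 0.332% in the same order.

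Th17 cultures were compared with naive cells to give the baseline for both ligands. Activation and polarization cannot be separated in it, because no activated culture without TGF-beta and IL-6 was analysed here. Time in culture and handling cannot be separated either, because naive cells were taken from tissue untreated and the Th17 cells spent 3 days in culture. Il17a and Il17f, the signature cytokines of the lineage, reached 86.5 ± 13.2 and 410 ± 73.2 CPM. Il17a had 0 counts in naive cells and was at least 424-fold higher, and Il17f, with 1 naive count, had a ratio of 6043 (95% counting interval 1084 to 238693). The ratio for the cytokine gene Il21 was 1492 (413 to 12321), from 2 naive counts. Ccl20, a chemokine gene, and Il23r, the receptor gene for IL-23, had 0 naive counts and were at least 352-fold and at least 27.2-fold higher. Of 22 tested members of the Th17 programme, 20 rose and 2 fell (camera adjusted p = 9.29e-19, adjusted p = 0.117 with an estimated correlation). Maf, a factor that drives Il10 and Il21, rose by 6.30 ± 0.14 on the log2 scale. The 2 that fell were Nfkbiz, which encodes the nuclear IkB protein IkBz (-2.23 ± 0.08), and Batf, an AP-1 factor (-0.82 ± 0.12). Il10 had a ratio of 203 (36.1 to 8036) from 1 naive count.

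Genes of dividing cells were higher in the Th17 cultures. Mki67, a proliferation marker, went from 14.5 ± 0.443 to 773 ± 70.8 CPM, and 30 of 31 cell cycle genes rose (adjusted p = 1.02e-26, adjusted p = 0.149 with an estimated correlation). The exception was Pcna, the sliding clamp of DNA replication, which fell (-0.98 ± 0.11). Of 14 replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, 13 rose and 0 fell, among them Hist1h1b by 4.96 ± 0.12 (adjusted p = 5.53e-09, adjusted p = 0.149 with an estimated correlation). This list was included as a sign of RNA quality, which cannot be told apart from cell division here. Cholesterol synthesis genes rose in 21 of 22 cases, such as Sqle, which encodes squalene epoxidase (2.26 ± 0.09), with adjusted p = 3.53e-06 and adjusted p = 0.300 with an estimated correlation. Other genes with the largest rises were Atp6v0d2, a subunit of the vacuolar proton pump, at least 1284-fold, the E3 ligase gene Peli2, at least 1118-fold, and Ahrr, the repressor of the aryl hydrocarbon receptor, at least 426-fold. These 3 had 0 naive counts. In the same libraries mitochondrial RNA took 15.9 ± 0.215% of reads against 10.9 ± 1.5% in naive cells, and ribosomal RNA 2.66 ± 0.129% against 1.99 ± 0.0998%.

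Genes of resting cells, interferon response and immediate early response fell. Of 25 naive and quiescence genes, 20 fell and 2 rose. Dapl1, a gene of resting T cells, changed by -7.96 ± 0.23 and Klf2, a factor that keeps T cells quiescent and recirculating, by -2.56 ± 0.08, while Bach2 (0.96 ± 0.09) and Igfbp4 (0.83 ± 0.08) rose. Of 28 interferon response genes, 25 fell and 2 rose. Irf7, the inducible interferon regulatory factor, changed by -4.30 ± 0.14, and Oas2 and Rsad2, antiviral effector genes, were at least 240-fold and at least 123-fold lower, with 0 counts in Th17. The guanylate-binding protein genes Gbp2 (3.95 ± 0.10) and Gbp3 (1.64 ± 0.12) rose. Of 21 AP-1 and immediate early genes, 17 fell and 3 rose, with Dusp5 at -6.27 ± 0.14 and Dusp1 at -4.72 ± 0.10 against Dusp4 at 3.67 ± 0.10, all 3 encoding phosphatases of MAP kinases. Adjusted p was 2.95e-10, 1.60e-09 and 5.22e-17 for these 3 lists, and adjusted p = 0.0636 with an estimated correlation for each. Heat shock genes fell in 10 of 12 cases and rose in 1 (adjusted p = 3.40e-05, adjusted p = 0.0774 with an estimated correlation), with the inducible HSP70 gene Hspa1b at -8.83 ± 0.24. This list was included as a sign of handling, which cannot be told apart from the change to Th17 here. Of 25 ribosome biogenesis genes 20 fell and 1 rose (adjusted p = 0.000529, adjusted p = 0.149 with an estimated correlation), including the nucleolar GTPase gene Gnl3 (-1.75 ± 0.11), while Wdr12 rose (1.28 ± 0.11).

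Of 26 NF-kB target genes, 16 fell and 8 rose (adjusted p = 0.0217, adjusted p = 0.149 with an estimated correlation). Tnfaip3, the NF-kB inhibitor A20, fell by 4.24, whereas Cd40, with 0 naive counts, was at least 162-fold higher. The median and the test of this list were negative and the mean of its fitted values positive, a mean that rests on genes with 0 naive counts such as Ccl20 and Cd40. Of 19 unfolded protein response genes 12 fell and 6 rose (adjusted p = 0.0287, adjusted p = 0.222 with an estimated correlation), with the chaperone gene Hspa5 at -2.08 ± 0.08. Both list calls ended without Th17 replicate 2, at adjusted p = 0.0516 for the NF-kB targets (0.00727 to 0.149 over all alternatives with camera) and 0.0538 for the unfolded protein response (0.00905 to 0.222). Fry, which tests against no change, gave 3.94e-05 and 0.000198.

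Both genes of the receptor pair for PAM3CSK4 fell, and Tlr6, not named above as a receptor of either ligand, rose. Values for Tlr4, the gene of the other receptor named for biglycan, are not given here. Tlr1, which pairs with Tlr2, fell from 66.6 ± 4.46 to 19.8 ± 1.20 CPM (-1.75 ± 0.12, adjusted p = 2.52e-11). Tlr2 fell from 4.07 ± 0.683 to 2.07 ± 0.0566 CPM (-0.98 ± 0.34, adjusted p = 0.0140), and Tlr6 rose from 3.83 ± 0.131 to 7.44 ± 1.77 CPM (0.96 ± 0.27, adjusted p = 0.00300). The Tlr2 call ended without naive replicate 2 (-0.79, adjusted p = 0.127), without Th17 replicate 2 (-0.96, adjusted p = 0.0505) and with DESeq2 (adjusted p = 0.0525), over a range of 0.0108 to 0.127. The Tlr6 call ended without Th17 replicate 1 (0.69, adjusted p = 0.0577, range 0.000178 to 0.0577). Of 22 TLR2 and MyD88 pathway components 7 rose and 9 fell, with no call for the list (adjusted p = 0.409; the median and the test were negative, the mean positive). Map3k7, the kinase TAK1, rose (0.87 ± 0.08) and Ikbkb, the kinase IKKb, fell (-1.52 ± 0.08).

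Of 17 regulatory T cell genes 10 rose and 5 fell (camera adjusted p = 0.000349, adjusted p = 0.0774 with an estimated correlation). Of 14 follicular helper genes 10 rose and 4 fell (adjusted p = 3.53e-06, adjusted p = 0.0636 with an estimated correlation). The Th1 list (6 of 14 rose, 6 fell) and the Th2 list (4 of 9 rose, 4 fell) were not called (camera adjusted p = 0.985 and 0.396). Among single genes of other T helper lineages, Gata3, the Th2 factor, fell (-1.96 ± 0.12). Foxp3, the regulatory T cell factor, was at 4.31 ± 0.0233 CPM in naive cells and 2.81 ± 0.397 CPM in Th17 (-0.62 ± 0.30, adjusted p = 0.0719). Il22 had 0 counts in all 8 libraries, which allows up to 0.0378 CPM, and Ifng had 7 counts in naive cells and 0 in the others. Of 6 tested CD8 T and NK cell markers 3 rose and 3 fell, with Prf1, the gene for perforin, at -4.43 ± 0.18 and Ctsw at 2.36 ± 0.11. All 4 tested myeloid markers fell, including Ctss (-0.47 ± 0.07). Of 5 B cell markers 1 rose and 4 fell, both tested gamma-delta markers rose, and the 1 tested red cell and platelet marker fell. For every list named in the comparison of Th17 with naive cells the counts adjusted over the list alone were the same as over all genes.

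In total 8390 of 11629 genes changed between Th17 and naive cells, 4395 higher and 3995 lower in Th17 (edgeR's quasi-likelihood test, Benjamini-Hochberg), with 2301 of them at least 2-fold higher and 1623 at least 2-fold lower. The libraries of the groups did not overlap for 84.0% of genes, against 33.3% by chance. Camera called 18 of 32 lists, 11 up and 7 down, and 0 with an estimated correlation. Its smallest adjusted p was then 0.0636, and fry called 30.

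PAM3CSK4 was compared with Th17 cultures without ligand to ask what a TLR2 ligand changed during polarization. Il17a was 1.75-fold higher, at 152 ± 37.5 against 86.5 ± 13.2 CPM (0.81 ± 0.13, adjusted p = 0.000392), or 0.54 without PAM3CSK4 replicate 4. Il17f was 1.74-fold higher at 716 ± 60.5 CPM (0.80 ± 0.10, adjusted p = 3.02e-05), and Il21 rose 1.65-fold. Lif, a cytokine of the IL-6 family, rose 2.23-fold from 26.0 ± 5.09 to 58.5 ± 5.52 CPM, and Ahr, the aryl hydrocarbon receptor, rose 2.05-fold. Il10 rose 2.42-fold (1.28 ± 0.23), but the value was 1.87 without Th17 replicate 1, and the call ended without PAM3CSK4 replicate 4 (0.84, adjusted p = 0.0579, range 3.42e-17 to 0.0579). The rise of Il23r (0.98 ± 0.30, adjusted p = 0.0444) became 1.82 without Th17 replicate 1 and ended without Th17 replicate 2 (0.49), without PAM3CSK4 replicate 3 (0.60), with robust estimation and with DESeq2 (range of adjusted p 4.67e-05 to 0.449). Of 22 genes of the Th17 programme 14 rose and 1 fell (16 and 1 adjusted over the list alone), with adjusted p = 1.17e-16 and adjusted p = 0.0676 with an estimated correlation. The plot of levels per library shows these genes in all 4 groups.

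**Figure D1:**
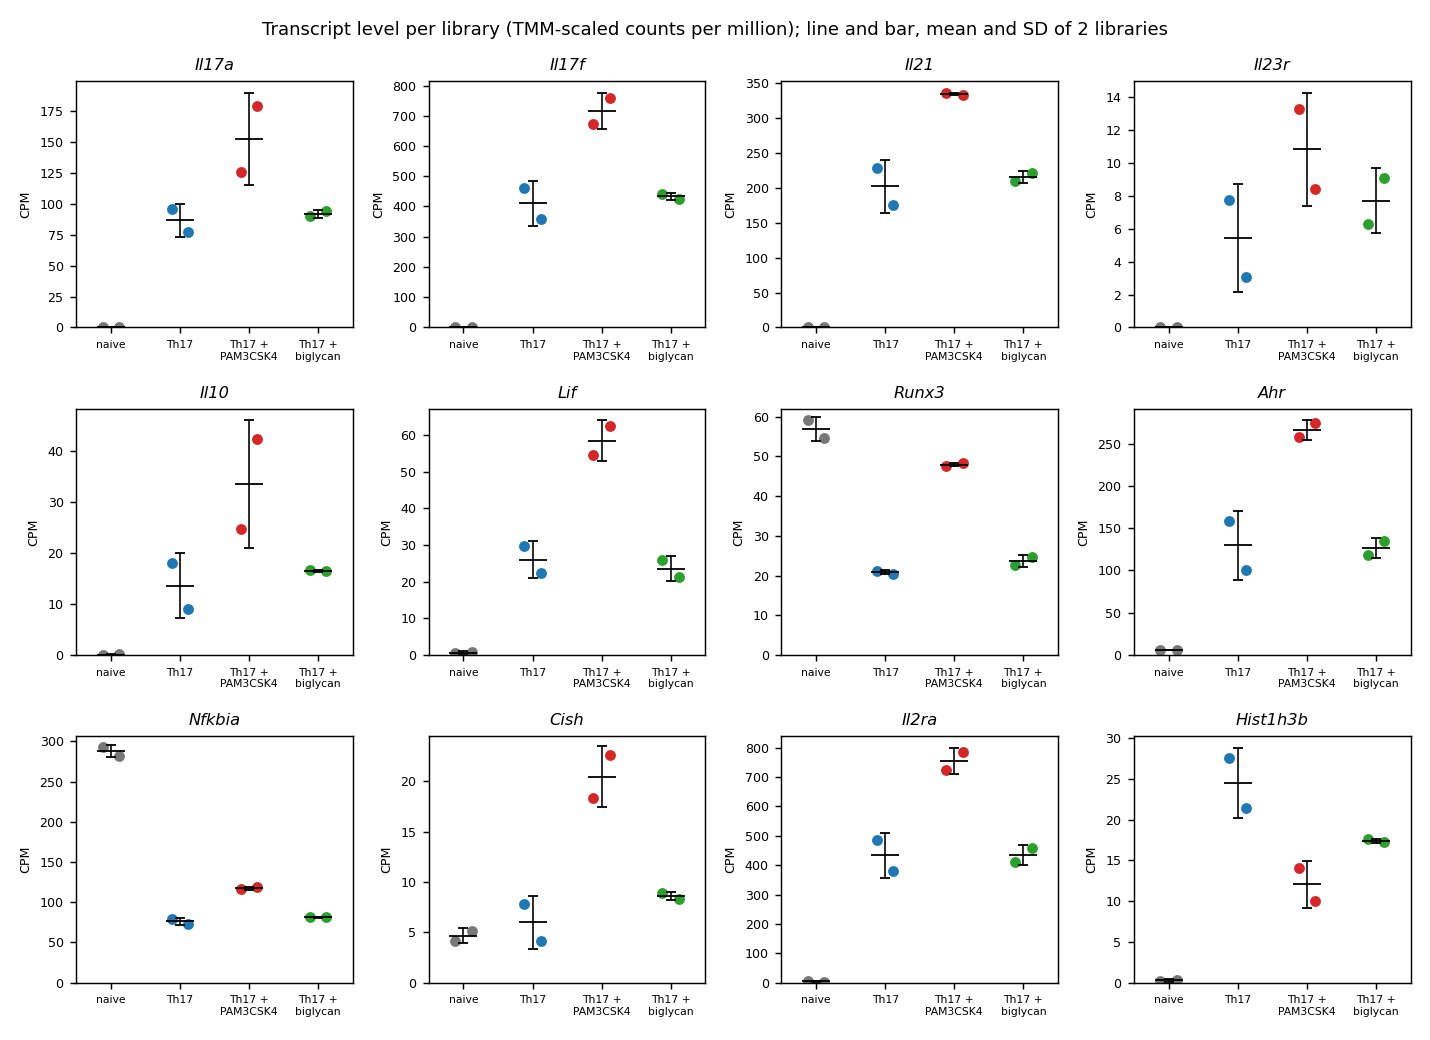
TMM-scaled CPM of 12 genes per library in naive cells, Th17 cultures and Th17 cultures with PAM3CSK4 or biglycan; each point is 1 library, the line is the mean of 2 libraries and the bar their SD. Il17a, Il17f, Il21, Lif, Ahr and Il2ra were higher in both PAM3CSK4 libraries than in all other libraries, and Hist1h3b was lower in them than in the Th17 and biglycan libraries.

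Some target genes of IL-2, IL-6, NF-kB and AP-1 signalling were higher with PAM3CSK4, and those of interferon and TGF-beta were not called as lists: 0 of 28 interferon response genes rose and 2 fell (1 and 3 adjusted over the list alone; adjusted p = 0.806), and 6 of 21 TGF-beta targets rose and 4 fell (8 and 4 adjusted over the list alone; adjusted p = 0.366). Cish, a feedback inhibitor of STAT5, rose 3.35-fold from 6.01 ± 2.61 to 20.5 ± 3.01 CPM, Il2ra, the high-affinity IL-2 receptor chain, 1.74-fold, and Ccnd2, a cyclin of G1 phase, 1.68-fold. Of 18 IL-2 and STAT5 target genes 11 rose and 0 fell (13 and 0 adjusted over the list alone), and this was the 1 list still called with an estimated correlation (adjusted p = 3.48e-12, adjusted p = 0.0447 with an estimated correlation). Il2 itself was at 2.27 ± 0.00965 against 1.04 ± 0.0357 CPM and did not pass (adjusted p = 0.0851; it passed in 1 of 11 alternatives, 0.0481 to 0.323). Of 18 IL-6 and STAT3 target genes 11 rose and 0 fell (12 and 0 adjusted over the list alone), with adjusted p = 3.48e-12 and adjusted p = 0.0547 with an estimated correlation. Nfkbia, the NF-kB inhibitor IkBa, rose 1.53-fold and Tnf 1.47-fold. Of 26 NF-kB target genes 9 rose and 0 fell (14 and 1 adjusted over the list alone), with adjusted p = 6.83e-08 and adjusted p = 0.0536 with an estimated correlation. Jun (0.78 ± 0.11) and Fosl2 (0.65 ± 0.09), subunits of AP-1, led the immediate early genes, of which 9 of 21 rose and 0 fell (11 and 0 adjusted over the list alone), with adjusted p = 1.26e-09 and adjusted p = 0.0799 with an estimated correlation.

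Some activation, glycolysis, cholesterol synthesis and ribosome biogenesis genes were also higher, while of 25 oxidative phosphorylation genes 0 rose and 1 fell (0 and 0 adjusted over the list alone; adjusted p = 0.612). Myc rose 1.77-fold, and of 25 T cell activation genes 11 rose and 1 fell (14 and 2 adjusted over the list alone), with adjusted p = 2.53e-09 and adjusted p = 0.0676 with an estimated correlation. The gene that fell was Lag3, an inhibitory receptor (-0.57 ± 0.10). Hk2, which phosphorylates glucose, rose 2.11-fold and Pfkl 1.44-fold, among 12 of 24 glycolysis and hypoxia genes that rose and 0 that fell (16 and 0 adjusted over the list alone; adjusted p = 1.23e-10, adjusted p = 0.0676 with an estimated correlation). Of 22 cholesterol synthesis genes 12 rose and 0 fell (the same adjusted over the list alone), with Lss, lanosterol synthase, up 1.44-fold (adjusted p = 7.63e-10, adjusted p = 0.160 with an estimated correlation). Of 25 ribosome biogenesis genes 11 rose and 0 fell (14 and 1 adjusted over the list alone), such as Wdr43 at 0.43 ± 0.08 (adjusted p = 2.87e-08, adjusted p = 0.0676 with an estimated correlation).

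Runx3, a Th1 and cytotoxic lineage factor, rose 2.29-fold, and the IL-12 receptor genes Il12rb1 and Il12rb2 rose 1.89-fold and 2.83-fold, the latter with a log2 change of 2.16 without Th17 replicate 1. These were the 3 of 14 Th1 genes that rose, and 0 fell (3 and 0 adjusted over the list alone; adjusted p = 0.000469, adjusted p = 0.0676 with an estimated correlation). Tbx21, the Th1 factor, was at 0.850 CPM with PAM3CSK4 and 1.19 in Th17 (adjusted p = 0.652), a log2 difference of -0.48 that was -0.77 without Th17 replicate 1, -0.14 without Th17 replicate 2, -0.24 without PAM3CSK4 replicate 3 and -0.73 without PAM3CSK4 replicate 4. Of 9 genes of non-pathogenic Th17 cells, which share members such as Il17a and Ahr with the Th17 programme, 4 rose and 0 fell (5 and 0 adjusted over the list alone). The adjusted p of that list was 0.000646 with camera, 0.0676 with an estimated correlation and 0.0177 with fry. Of 15 genes of pathogenic Th17 cells 2 rose and 1 fell (5 and 1 adjusted over the list alone), with Bhlhe40 at 0.47 ± 0.08. That list call, at adjusted p = 0.0478, ended without Th17 replicate 2 (0.357), without PAM3CSK4 replicate 3 (0.0752), with fry (0.0781) and at adjusted p = 0.232 with an estimated correlation. Csf2, which encodes GM-CSF, was at 1.85 ± 0.839 against 0.658 ± 0.383 CPM and did not pass (1.42, adjusted p = 0.0997; 2.20 without Th17 replicate 1 and 0.89 without PAM3CSK4 replicate 4). The largest rises included Mmp10, a matrix metalloproteinase (5.75-fold), the nuclear lamina gene Lmna (3.20-fold) and the transglutaminase gene Tgm2 (1.65 ± 0.21, but 2.34 without Th17 replicate 1, and adjusted p = 0.0646 with robust estimation, range 4.51e-46 to 0.0646). The largest falls included Akr1c18, a progesterone-metabolizing enzyme (-2.03 ± 0.32), Rasgrp3, an activator of Ras (-1.81 ± 0.18), and Tubb3 (-1.67 ± 0.20).

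Histone genes and part of the naive and follicular helper genes fell with PAM3CSK4. Of 14 replication-dependent histone genes 9 fell and 0 rose (11 and 0 adjusted over the list alone), with adjusted p = 1.06e-09 and adjusted p = 0.107 with an estimated correlation. Hist1h3b went from 24.5 ± 4.28 to 12.0 ± 2.83 CPM. The histone list was included as a sign of RNA quality, and a difference in RNA quality or capture between the libraries was not tested for it. The cell cycle list, of which 4 genes fell and 1 rose out of 31 (8 and 1 adjusted over the list alone), was called down at adjusted p = 0.000593, with adjusted p = 0.491 with an estimated correlation, 0.209 with fry and 0.661 without PAM3CSK4 replicate 4. Of 25 naive and quiescence genes 8 fell and 0 rose (10 and 2 adjusted over the list alone), with adjusted p = 0.00230 and adjusted p = 0.138 with an estimated correlation. Its member Pecam1 (-0.49 ± 0.10) was not called without Th17 replicate 2 (-0.27) or PAM3CSK4 replicate 4 (-0.41). Tox, a factor of follicular helper and exhausted cells, fell 2.00-fold, among 4 of 14 follicular helper genes that fell and 1 that rose (the same adjusted over the list alone; adjusted p = 0.382). The mitochondrial RNA share was 14.5 ± 0.322% in these libraries and 15.9 ± 0.215% in Th17.

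No component of the TLR2 and MyD88 pathway passed the test with PAM3CSK4: 0 of 22 rose or fell, also adjusted over the list alone (edgeR's quasi-likelihood test; camera adjusted p = 0.420, fry 0.0614). Myd88 was at 67.0 ± 2.89 against 55.6 ± 6.46 CPM (0.27, adjusted p = 0.107; 0.16 without Th17 replicate 2). Sigirr, an inhibitory member of the receptor family, was at 121 ± 2.10 against 101 ± 1.82 CPM (adjusted p = 0.0581, under 0.05 in 2 of 12 alternatives, 0.0162 to 0.300). Tlr2 was at 2.34 ± 0.532 against 2.07 ± 0.0566 CPM (0.16 ± 0.34), and this difference was -0.08 without PAM3CSK4 replicate 4. Of the markers of other cells, 1 of 5 B cell genes and 1 of 6 CD8 T and NK cell genes rose, and 0 of 4 myeloid genes changed; adjusted over the list alone, 2 B cell genes and 1 CD8 T and NK cell gene rose and 2 myeloid genes fell. The B cell gene was H2-Ab1, an MHC class II chain, at 11.2 ± 1.01 against 4.25 ± 2.46 CPM (1.37 ± 0.26; 2.15 without Th17 replicate 1 and 0.90 without Th17 replicate 2).

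In total 1162 genes changed with PAM3CSK4, 606 higher and 556 lower (edgeR's quasi-likelihood test, Benjamini-Hochberg). The median size of their log2 changes was 0.45, and 48 were at least 2-fold higher and 68 at least 2-fold lower. The libraries did not overlap for 53.0% of tested genes, against 33.3% by chance. Camera called 19 of 32 lists, 16 up and 3 down, and 1 with an estimated correlation; fry called 21. The count was 361 without Th17 replicate 2, 387 without PAM3CSK4 replicate 4 and 594 without PAM3CSK4 replicate 3.

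**Figure D2:**
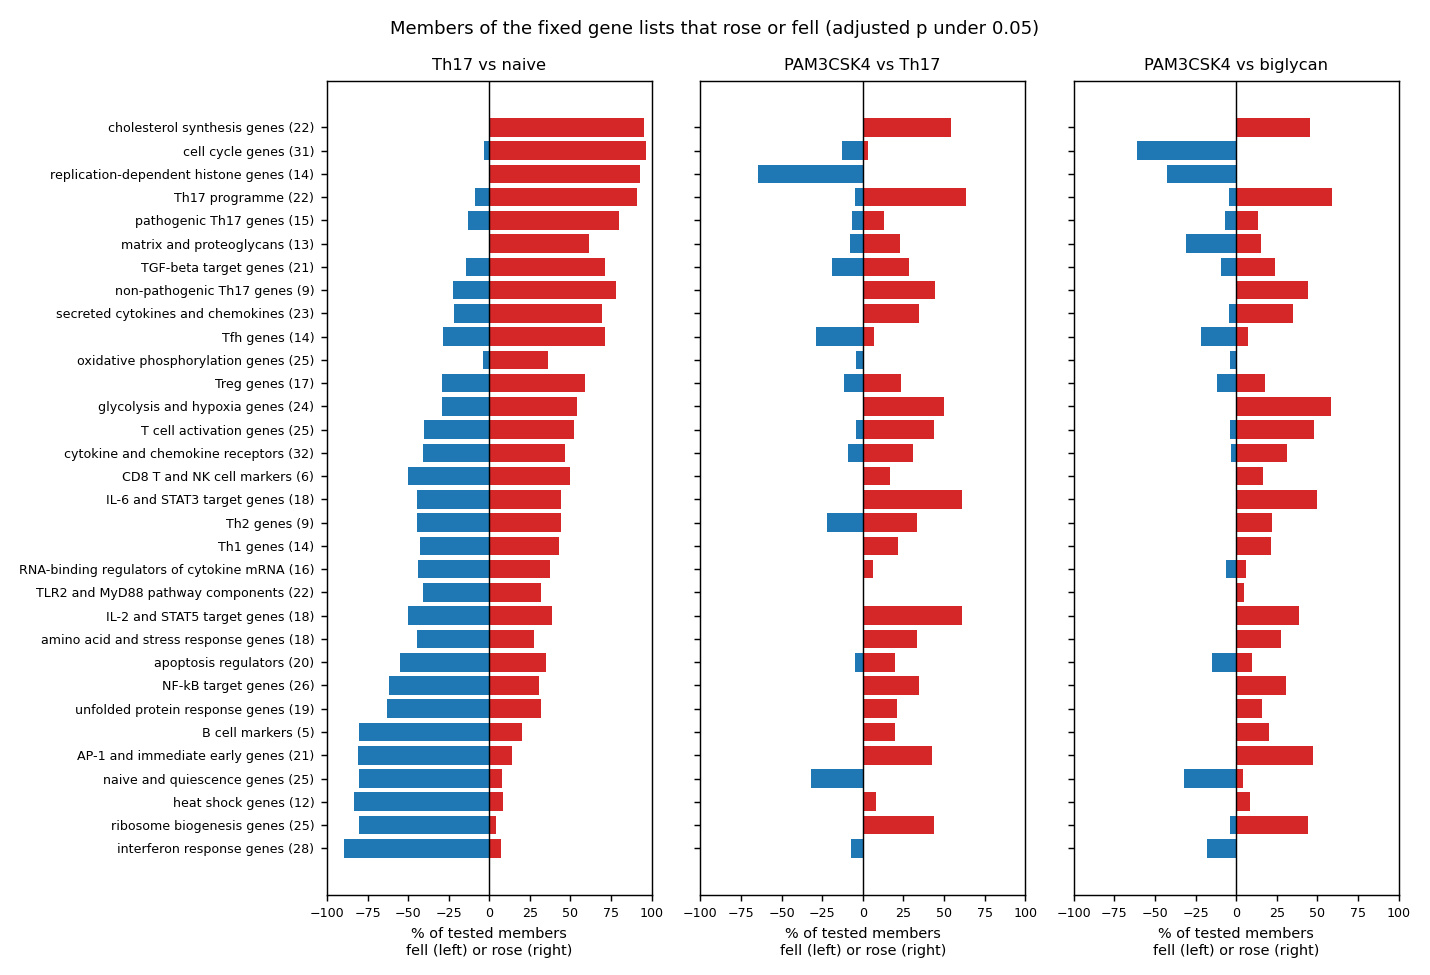
Percent of the tested members of each fixed gene list (number in brackets) that rose (right) or fell (left) at adjusted p under 0.05, in Th17 against naive cells, PAM3CSK4 against Th17 and PAM3CSK4 against biglycan. The cell cycle list rose in 30 of 31 members in Th17 against naive cells and fell in 19 of 31 with PAM3CSK4 against biglycan.

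Biglycan was compared with Th17 cultures without ligand to ask the same of a matrix-derived ligand. Il17a was at 92.0 ± 3.17 against 86.5 ± 13.2 CPM (0.09 ± 0.13, 95% interval -0.18 to 0.36), Il17f at 433 ± 10.4 against 410 ± 73.2 (0.08 ± 0.10, -0.13 to 0.28) and Il21 at 215 ± 8.21 against 202 ± 37.8 (0.09 ± 0.10, -0.11 to 0.29). Without Th17 replicate 2 these differences were -0.06, -0.09 and -0.09, and without Th17 replicate 1 they were 0.26, 0.28 and 0.30. Il10 and Il23r, at 0.26 ± 0.26 and 0.48 ± 0.32, were -0.13 and -0.01 without Th17 replicate 2 and 0.86 and 1.31 without Th17 replicate 1. Of the 22 genes of the Th17 programme 0 rose or fell, also adjusted over the list alone (adjusted p = 0.910). The genes with the smallest p among higher ones were Cyp1b1, a target of the aryl hydrocarbon receptor (0.73 ± 0.14, adjusted p = 0.160), Sh3bp5 (0.52 ± 0.10) and Pim1, a kinase gene induced by cytokines (0.34 ± 0.08). The genes with the smallest p among lower ones were the small nucleolar RNAs Snord49b (-2.24 ± 0.37, adjusted p = 0.0828), Snora61 (-1.39 ± 0.25) and Snord15b (-0.72 ± 0.14, but -0.46 with offsets for GC content and length), which guide modifications of ribosomal and other RNA. They lie inside other genes, and their counts are uncertain. Of 12 alternatives Snord49b passed in 3 (8.53e-07 to 1.00), Snora61 in 2 (3.96e-07 to 1.00), Cyp1b1 in 2 (7.26e-07 to 0.555), Snord15b in 1 (7.26e-07 to 1.00) and Sh3bp5 in 1 (0.00433 to 1.00), each of them without a filter on low counts. Leaving out Th17 replicate 2 gave calls for Snord49b (0.0148) and Snora61 (0.00389), and leaving out Th17 replicate 1 for Cyp1b1 (0.0269).

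No gene changed with biglycan by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment: 0 genes passed, with 0 by DESeq2, 29 without a filter on low counts (14 higher, 15 lower) and 507 at an unadjusted p under 0.05 against 581 by chance. The libraries did not overlap for 34.2% of genes, against 33.3% by chance. Leaving out a library gave 1 gene (Th17 replicate 1), 4 (Th17 replicate 2), 2 (biglycan replicate 7) and 6 (biglycan replicate 8). Camera called 2 lists up. The cell cycle genes, with 0 of 31 passing, had a median of 0.19 (adjusted p = 6.62e-15, adjusted p = 0.676 with an estimated correlation, 0.700 with fry), with Mki67 at 0.31 ± 0.09. The IL-2 and STAT5 targets, with 0 of 18 passing (2 rose adjusted over the list alone), had adjusted p = 0.00684, adjusted p = 0.606 with an estimated correlation and 0.350 with fry, and their call ended without Th17 replicate 2 (0.305) and without biglycan replicate 7 (0.0510). The directions turned with the library left out: camera called 8 lists up and 0 down without Th17 replicate 1, but 2 up and 6 down without Th17 replicate 2. It called 1 up without biglycan replicate 7, and 4 up and 2 down without biglycan replicate 8. Fry called 1 list, the interferon response genes (0.0151, camera 0.152), and neither of those called by camera.

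The ligands were then compared with each other, which tests directly whether their cultures differed. Il17a (0.72 ± 0.13, adjusted p = 0.000971; 0.45 without PAM3CSK4 replicate 4), Il17f (0.72 ± 0.10) and Il21 (0.64 ± 0.09) were higher with PAM3CSK4 than with biglycan. So were Lif (1.31 ± 0.14), Rora, a nuclear receptor gene (0.75 ± 0.08), and Ahr (1.07 ± 0.13). Of 22 genes of the Th17 programme 13 were higher and 1 lower (15 and 1 adjusted over the list alone), with adjusted p = 8.88e-15 and adjusted p = 0.0999 with an estimated correlation. Jun (0.97 ± 0.11) and Fosl2 (0.75 ± 0.09) were among 10 of 21 immediate early genes that were higher, with 0 lower (11 and 0 adjusted over the list alone; adjusted p = 9.24e-11, adjusted p = 0.0969 with an estimated correlation). Nfkbia (0.53 ± 0.08) and Tnf (0.55 ± 0.09) were among 8 of 26 NF-kB targets that were higher, with 0 lower (9 and 0 adjusted over the list alone; adjusted p = 5.83e-06, adjusted p = 0.0651 with an estimated correlation). Aldoc, a glycolytic aldolase (0.94 ± 0.13), was among 14 of 24 glycolysis and hypoxia genes that were higher, with 0 lower (18 and 0 adjusted over the list alone; adjusted p = 1.41e-10, adjusted p = 0.0969 with an estimated correlation).

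Cell cycle genes were lower with PAM3CSK4 than with biglycan in 19 of 31 cases and higher in 0 (22 and 0 adjusted over the list alone; adjusted p = 2.67e-13, adjusted p = 0.196 with an estimated correlation). Kif20a, a mitotic kinesin, differed by -0.51 ± 0.08 and Ccna2, cyclin A2, by -0.50 ± 0.09. Of 14 histone genes 6 were lower and 0 higher (8 and 0 adjusted over the list alone; adjusted p = 4.48e-08, adjusted p = 0.140 with an estimated correlation), including Hist1h1b at -0.62 ± 0.08. Here too a difference in RNA quality was not tested for the histone list. By the naming rule the largest falls were those of Akr1c18 (-2.21 ± 0.32), Sv2c, a synaptic vesicle protein gene (-1.74 ± 0.24), and Rasgrp3 (-1.66 ± 0.18), and the largest rise was that of Tgm2 (1.87 ± 0.22). Sparc, a matrix glycoprotein, was lower with PAM3CSK4 (-4.47 ± 0.92), but its values were 66 counts in biglycan replicate 7 and 10 in replicate 8. Its call ended without biglycan replicate 7 (-2.57, adjusted p = 0.256, range 4.71e-12 to 0.256) and with robust estimation (0.0585), and the difference was -5.26 without biglycan replicate 8, -3.82 without PAM3CSK4 replicate 3 and -5.46 without PAM3CSK4 replicate 4. Csf2 was at 1.85 ± 0.839 CPM with PAM3CSK4 and 0.422 ± 0.151 with biglycan (adjusted p = 0.0312), and not called without PAM3CSK4 replicate 4 (0.335), biglycan replicate 7 (0.278) or biglycan replicate 8 (0.12; range 0.0115 to 0.335).

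In total 1342 genes differed between the ligands, 658 higher and 684 lower with PAM3CSK4, of which 44 and 63 by at least 2-fold (edgeR's quasi-likelihood test, Benjamini-Hochberg). The libraries did not overlap for 58.9% of genes, against 33.3% by chance. Camera called 18 of 32 lists, 15 up and 3 down, and 0 with an estimated correlation; fry called 22. The count was 777 without PAM3CSK4 replicate 3, 449 without PAM3CSK4 replicate 4, 360 without biglycan replicate 7, 625 without biglycan replicate 8, 894 with DESeq2 and 2231 with only the 4 libraries compared.

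Of the genes that changed with PAM3CSK4 against either group, 840 were called in both comparisons in the same direction and 0 in opposite directions. Both comparisons share the PAM3CSK4 libraries. In a split chosen after the data were seen, with replicate 3 against Th17 and replicate 4 against biglycan, 245 genes were called in both in the same direction, and 265 the other way round, with 0 in opposite directions. The correlation without a shared library was 0.372 and 0.325, against 0.00597 ± 0.0418 and 0.00749 ± 0.0399 in simulated unchanged groups. With both libraries in both comparisons, across genes the changes in both had a correlation of 0.705 and a covariance of 0.103, against 0.466 ± 0.0368 and 0.0262 ± 0.00282 in unchanged groups simulated with the same sharing (SD of 20 draws). A further 322 genes were called against Th17 only and 502 against biglycan only. Across genes, which are not independent replicates, the changes with PAM3CSK4 and with biglycan against the shared Th17 libraries had a correlation of 0.302. Unchanged groups gave 0.492 ± 0.0328 (SD of 20 draws), where the 2 shared Th17 libraries were also simulated from the Th17 mean. The measured gap between the 2 Th17 libraries enters these draws only through the estimated spread per gene. The covariance was 0.0330 against a simulated 0.0281 ± 0.00265. The SD across genes was 0.369 for the changes with PAM3CSK4 and 0.296 for those with biglycan. The simulated SDs were 0.233 ± 0.00545 and 0.245 ± 0.00656, and a larger SD lowers the correlation at the same covariance. Over genes with at least 5 CPM the correlation was 0.223 against 0.494 ± 0.0195 and the covariance 0.00831 against 0.00940 ± 0.000463. The correlation was 0.549 without Th17 replicate 1 and 0.470 without Th17 replicate 2, where the simulated groups gave 0.698 ± 0.0177 and 0.673 ± 0.0244. It was 0.187 without PAM3CSK4 replicate 4 and 0.167 without biglycan replicate 8, against simulated 0.402 ± 0.0285 and 0.371 ± 0.0314.

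**Figure D3:**
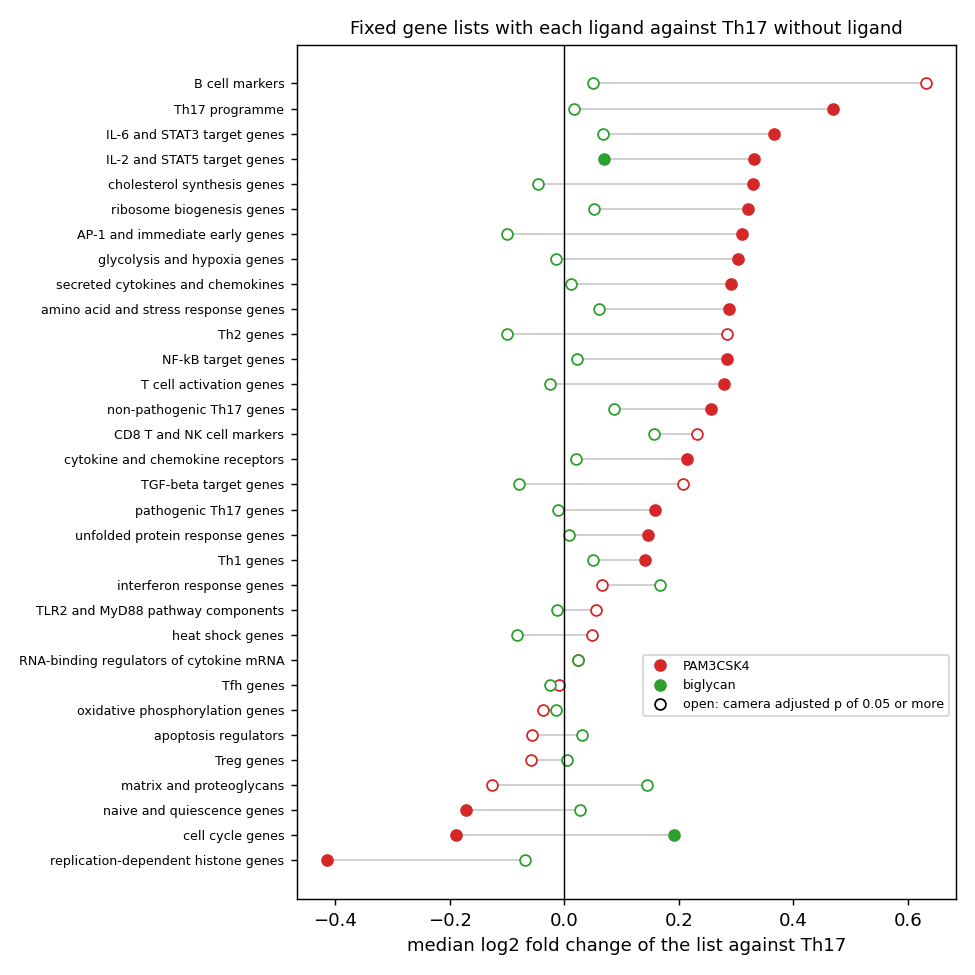
Median log2 fold change of the tested members of each fixed gene list against Th17 cultures, for PAM3CSK4 and biglycan; points are filled where the camera adjusted p is under 0.05 and open otherwise. The list of IL-2 and STAT5 target genes is filled for both ligands and the cell cycle list on opposite sides of 0; with an estimated correlation adjusted p was 0.606 for the former with biglycan, and 0.676 with biglycan and 0.491 with PAM3CSK4 for the latter.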

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

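The tests on stromal markers under 1 CPM in both Th17 libraries and the test on other short RNAs were chosen only after the result was seen, and so were the offsets for GC content and length. The separate sum of myeloid and B cell markers under 20 CPM was not part of the expectation written beforehand.

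In the deposited mapping tables and the summary lines of the count table, which no comparison used, 3 shares were higher in both Th17 libraries than in both naive libraries. They were ribosomal RNA (2.66% against 1.99%), mitochondrial RNA (15.9% against 10.9%) and the line for reads without a unique alignment (76.0% against 74.4%). The last is a share of the count table's total, which exceeds the number of read pairs, and not a share of reads. No explanation was tested for these 3 shares.

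Transcripts of connective tissue were uneven between the biglycan libraries: replicate 7 had 32 counts of Bgn, the gene for biglycan itself, 64 of Acta2, a smooth muscle actin, and 59 of Col3a1, a fibrillar collagen, against 2, 7 and 6 in replicate 8; the genes other than Bgn were chosen after their values were seen. The first test, on 26 stromal markers, gave a ratio of 1.32 between replicates 7 and 8, which met the bound set beforehand against carried-over cells, and a sum of 214 CPM in replicate 8, which lay under the 272 CPM of Th17 replicate 2 and so met the bound set beforehand against a response shared by both cultures. Both bounds were wrong, because Thbs1, which had 2681 and 2442 counts in the Th17 libraries and 20 and 14 in the naive ones, held 84.4% of the marker counts of replicate 8. Over the 19 markers under 1 CPM in both Th17 libraries the ratio was 4.60 (counting interval 3.45 to 6.24), so RNA from fibroblasts or smooth muscle cells may have entered replicate 7, although the labels say that naive cells were sorted before culture. A response shared by both biglycan cultures cannot be told apart by the sum in replicate 8, 6.03 CPM, which lay level with the 6.00 CPM of Th17 replicate 2. The sum was 27.8 CPM in biglycan replicate 7, the highest of the 8 libraries, but other pairs were uneven too. It was 8.36 and 2.15 CPM in naive replicates 1 and 2, 3.38 in Th17 replicate 1, and 2.51 and 3.35 with PAM3CSK4.

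Small nucleolar RNAs were mostly lower with biglycan: 59 of 70 tested were below Th17, 22 of them at an unadjusted p under 0.05 and 0 by edgeR's adjusted test, with a median of -0.61. The median ran from -0.43 without Th17 replicate 1 to -0.77 without Th17 replicate 2, and with PAM3CSK4 it was -0.16, with 42 of 70 lower, 13 of them at an unadjusted p under 0.05, and 5 of 70 passing the adjusted test. The median of 14 host genes was -0.0689, within its half-width of 0.0851, and that of 32 other short RNAs was -0.24 with a half-width of 0.20. The small nucleolar RNAs had a median of -0.61 with a half-width of 0.36. Set beside it, the host median argues against lower host expression as the whole cause, for these 14 hosts. A part of it stays open, because the host median passed the bound against it by less than its half-width. Lower recovery of short RNA stays open, because the other short RNAs were below 0 but not by as much as that explanation needed. In Th17 against naive 42 of the 70 fell and 3 rose, and the summed level was 889 and 996 CPM in naive, 616 and 575 in Th17, 414 and 544 with PAM3CSK4, and 583 in biglycan replicate 7 and 331 in replicate 8; the ribosomal RNA share was also lower in both biglycan libraries (1.43 and 1.90%) than in Th17 (2.57 and 2.75%), and no biological explanation was tested.

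For the genes changed by PAM3CSK4, 95.2% stayed called in the same direction with offsets for GC content and transcript length, which argues against such a trend as the whole cause. The summed level of myeloid and B cell markers went from 314 to 295 CPM, -0.0836% of the 22189 CPM by which the genes called higher rose. This fall came from the markers with a high level in Th17: the 30 of 32 under 20 CPM there went from 20.6 to 31.1 CPM, 0.0474% of that rise and 0.0581% between the extreme libraries. Both shares lie far under the bound, set beforehand for the sum of all markers, which argues against RNA from those cells as the whole cause, while a small rise of such RNA stays open. Differences between cultures other than the ligand were not tested, because each group had 2 libraries and the labels give no batch.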

How the results depend on the processing

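The offsets for GC content and length and the split of the PAM3CSK4 libraries were chosen only after the result was seen.

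For Th17 against naive the count of changed genes stayed within 1.5 times under every alternative run, from 7748 with DESeq2 to 8625 without a filter, with 8051 genes and 19 lists with the replicate block and 7793 to 8147 when leaving out a library. For PAM3CSK4 against Th17 it was 777 with DESeq2 and 361 to 938 when leaving out a library, the lowest without Th17 replicate 2. For PAM3CSK4 against biglycan it was 894 with DESeq2, 2231 with only the 4 libraries compared and 360 to 777 when leaving out a library. For biglycan against Th17, with 0 genes by edgeR and by DESeq2, it was 1 with library totals, 29 without a filter, 1 with the GC and length offsets and 1 to 6 when leaving out a library. The cause was not tested for any of these.

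With an estimated correlation 0, 1, 0 and 0 lists were called for Th17 against naive, PAM3CSK4 against Th17, biglycan against Th17 and PAM3CSK4 against biglycan. With fry 30 were called for Th17 against naive and 1 for biglycan, not among the 2 called by camera. With camera, leaving out a library gave 1 to 8 for biglycan. The correlation between the ligands' changes, 0.302, was 0.444 without a filter, 0.223 over genes with at least 5 CPM (simulated 0.494 ± 0.0195) and 0.167 to 0.549 when leaving out a library (simulated 0.371 to 0.698); the cause was not tested. Both PAM3CSK4 comparisons called 840 genes in the same direction. The split without a shared library, made in separate fits, gave 245 and 265 such genes. How many of those were among the 840 was not counted.

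Leaving out a library, the biglycan differences ran from -0.0551 to 0.256 for Il17a, -0.0889 to 0.276 for Il17f, -0.0857 to 0.296 for Il21, -0.00911 to 1.31 for Il23r and -0.13 to 0.861 for Il10, reversed without Th17 replicate 2 and highest without Th17 replicate 1. That of Tlr2 with PAM3CSK4 ran from -0.0793, reversed, without PAM3CSK4 replicate 4 to 0.386 without PAM3CSK4 replicate 3. None of them was called, and the cause was not tested. Depth limits genes near the floor, where 3 counts in a library correspond to 0.239 to 0.428 CPM.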

Other observations

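The hypothesis below and its test were set before their result was seen.

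Since PAM3CSK4 raised Il17a, Il17f and Il21 above biglycan, cultures with PAM3CSK4 might lie further along the difference between naive and Th17 cells. Of 1142 genes called both in PAM3CSK4 against biglycan and in Th17 against naive, comparisons that share no library, 41.1% changed in the same direction, against 49.4% expected from the totals. Of the rest, 433 were lower with PAM3CSK4 and higher in Th17, and 240 were the reverse. The test argues against a general shift along that difference. It does not bear on the Th17 programme alone. Of its 22 genes 20 rose and 2 fell in Th17 against naive cells, and 13 were higher and 1 lower with PAM3CSK4 than with biglycan.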
